A study of Mus musculus with 16 samples.

How the data were processed

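RNA sequencing was done on liver of 16 C57BL/6N mice in 4 groups of 4, set by diet and by DEN or vehicle injection, per the labels. RNA was extracted with Trizol and libraries were made with a stranded mRNA kit, per the labels' protocols. FastQC, Trimmomatic, HISAT2 and HTSeq 0.11.1 and the mouse genome build GRCm38 are listed in the submitters' processing notes, which give no role or order and no setting for strand.

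The deposited table holds 1 row per gene, with Ensembl identifiers and symbols. Per the file headers, it gives the authors' mean normalized count, a signal that is never negative, and the authors' log2 fold change with its standard error, also on the log2 scale. It further gives the authors' test statistic, a score, and the authors' p-value with its adjusted p-value. The headers are those of a DESeq2 results table by name, and the tool, the model, the samples and the sides of the comparison are not given in the sources used here. The 16 value columns headed by library codes match no label of any sample, so they were not used in any step. Checked on the values, the statistic equals the fold change divided by its standard error, the p-value is the 2-sided normal p of that statistic, and the adjusted p-value is the Benjamini-Hochberg value over the genes that have one. Those are 16288 genes with a mean normalized count of at least 2.949, and the 14175 genes without an adjusted p have at most 2.947.

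Because no library could be matched to a group, the 7 comparisons planned before the data were examined, which were the effects of diet, of DEN and of their combination, were not run. No value per sample, standard deviation, depth per sample or own test between groups is given, and the precision of each value is the authors' standard error. The authors' deposited table was analysed in their place. Its p-values rest on the authors' model and could not be recomputed from libraries.

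A gene was called at an adjusted p-value below 0.05 in the authors' deposited table. Intervals are 95% normal intervals from the authors' standard error. The count adjusted over the list alone applies Benjamini-Hochberg to the authors' p-values of the list's tested members. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' statistic, two-sided and against all other tested genes, with a preset correlation between genes of 0.01. A list needed 4 tested members. Of 50 lists fixed before the data were examined, 48 were tested, and their p-values were adjusted with Benjamini-Hochberg over the lists. A correlation cannot be estimated without values per sample, so presets of 0.05 and 0.10 were tried in its place. With 0.05, 17 of the 20 called lists passed, and with 0.10, 10 did. The fixed plan was to name genes by a minimum on normalized counts per library and by separation of the groups, which needs libraries. The rule was therefore adapted to the 6 widest changes per direction among called genes with a mean normalized count of at least 102 (a fixed small share of the sum over all genes), the 2 called members with the smallest p of each of the 10 lists with the smallest p, and the genes of a panel of 12 for diet and a panel of 6 for DEN, giving 41 genes, some of which are not reported here.

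Gene positions, lengths and GC content came from GENCODE release M21 on GRCm38, matched by Ensembl identifier for 30388 of 30463 genes (99.8%). Of the list symbols, 21 were absent from the table and 3 were found under another current name. A trend of the statistic on GC content, log2 transcript length and log2 mean count was fitted with splines of 4 degrees of freedom each over the 99.9% of tested genes with a value, and it accounted for 7.04% of the variance. The correlation of the statistic across genes was 0.083 with GC content and -0.20 with log2 length, where genes are not independent replicates. The steps were tested on simulated statistics for 16288 genes, of which 200 were changed. Calls recovered 41.8% of genes changed 1.5-fold, 76.1% at 2-fold and 92.4% at 4-fold, with 6 false calls. Of 500 simulated lists without change 0.8% were called, and of 100 lists of 20 genes with 8 changed members 100% were called. These rates hold for the simulated settings alone, since the correlation between genes in the data could not be estimated. Alternatives were other adjustments, count minimums, thresholds, presets of the correlation, ranks, a scaled statistic and the statistic with the trend removed.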

Results

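The study measured gene expression by RNA sequencing of whole liver from wild-type C57BL/6N mice aged 14 weeks. Mice received vehicle or diethylnitrosamine (DEN), an alkylating liver carcinogen that cytochrome P450 enzymes activate, at 2 weeks of age. From 6 weeks of age they stayed on control diet or were switched to a diet labelled 60% high fat. The 16 samples fall into 4 groups of 4, which are vehicle on control diet, DEN on control diet, vehicle on high fat diet and DEN on high fat diet. The title of the series asks how non-transformed cells respond to fat, and whether they induce glucose metabolism.

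The values analysed are those of 1 comparison made by the authors. Their deposited table gives, for 30463 genes, a mean normalized count, a log2 fold change with its standard error (SE), and a p-value. The table does not name the sides of that comparison, so a positive log2 fold change is described as higher on the positive side and a negative one as higher on the negative side. The depth of each sample and its spread are not given here, because the per-library columns could not be matched to samples. The mean normalized counts sum to 20403700 over all genes.

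Genes of lipid storage were higher on the positive side of the comparison, together with genes of ketone body synthesis and, with calls that were lost when the correlation between genes was preset at 0.10, genes of fatty acid oxidation. Genes of amino acid breakdown and the urea cycle were higher on the negative side, as were female-biased liver genes and periportal genes. The periportal and amino acid lists share members such as Cps1 and Gls2. Gluconeogenic and cell cycle genes were also called on the negative side as lists, the former not with ranks in place of the statistic and the latter not among genes with a mean normalized count of at least 100. Among called genes with a mean normalized count of at least 102, the widest difference was that of Cidea, a lipid droplet protein, at a log2 fold change of 8.20 ± 0.64 (SE), or 293.7-fold, in the authors' deposited table. Glycolysis genes as a list did not pass the test (adjusted p = 0.162). Only among genes with a mean normalized count of at least 100 did that list pass, on the positive side (adjusted p = 0.0438).

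Of 16288 genes with an adjusted p in the authors' deposited table, 1070 (6.57%) were below 0.05, with 598 positive and 472 negative. A change of at least 2-fold was seen for 157 of the positive and 115 of the negative genes. The median absolute log2 fold change of the 1070 genes was 0.56, and the median log2 fold change of all tested genes was -0.0044. At an unadjusted p under 0.05 there were 3102 genes, where chance alone gives 814. Dividing every statistic by the median absolute deviation of all statistics (1.44) left 142 genes.

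**Figure D1:**
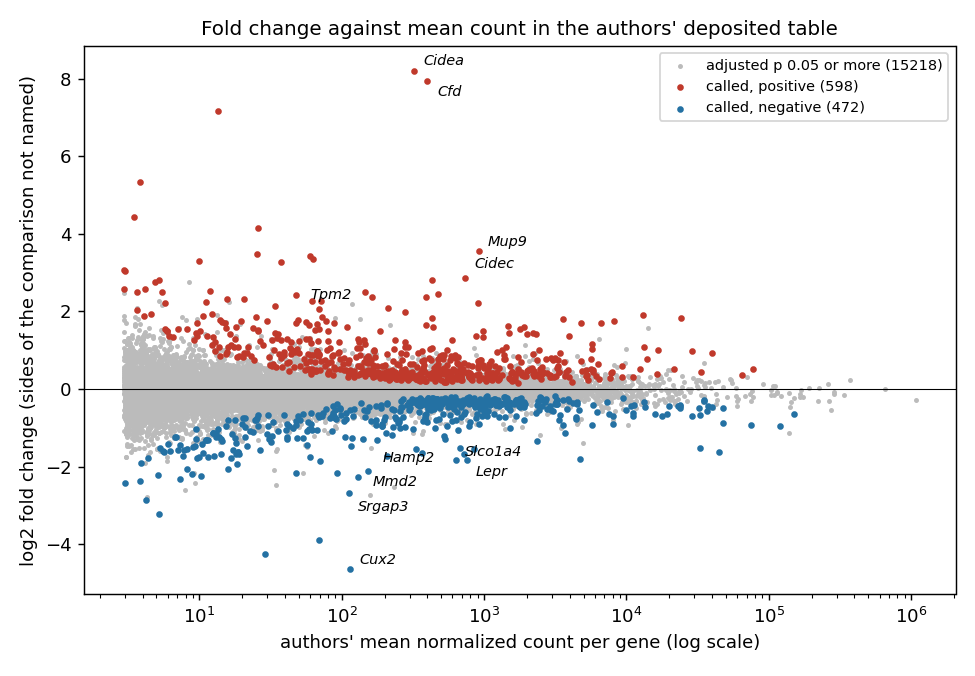
Log2 fold change of each tested gene (vertical axis) against the authors' mean normalized count (horizontal axis, log scale). Red and blue points are the 598 positive and 472 negative genes with an adjusted p below 0.05, grey points are the other tested genes, and genes among the widest changes of well expressed genes are named.

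Among called genes with a mean normalized count of at least 102, the widest positive change after Cidea was that of Cfd, which encodes the secreted protease adipsin. Its log2 fold change in the authors' deposited table was 7.93 ± 0.69 (SE, adjusted p = 2.6e-26). Cidea (ENSMUSG00000024526) lies on chromosome 18 from 67343604 to 67367785, and Cfd (ENSMUSG00000061780) on chromosome 10 from 79890853 to 79892655, in GRCm38. B430212C06Rik, a gene annotated on the opposite strand and overlapping Cidea, had a log2 fold change of 7.16 ± 0.81 (SE) in the authors' deposited table. Its mean normalized count there was 13.46, beside 323.63 for Cidea. Whether counting used strand is not given in the sources used here, so reads of the overlap cannot be assigned to either gene. Mup9, a major urinary protein gene on chromosome 4 from 60418046 to 60421952, followed at 3.55 ± 0.38 (log2, SE) in the authors' deposited table, a value that is uncertain because near-identical Mup copies share reads. Cidec, a lipid droplet protein, was at 2.88 ± 0.54 and the tropomyosin gene Tpm2 at 2.50 ± 0.29 (log2, SE, authors' deposited table).

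The widest negative change in this class was that of Cux2, a transcription factor with female-biased expression in liver, at -4.64 ± 0.78 (log2, SE, adjusted p = 8.1e-07) in the authors' deposited table. Cux2 (ENSMUSG00000042589) lies on chromosome 5 from 121856366 to 122050102 in GRCm38. Srgap3 was at -2.67 ± 0.32, Mmd2 at -2.27 ± 0.43 and Hamp2, a hepcidin gene, at -2.10 ± 0.56 (log2, SE) in the authors' deposited table. Slco1a4, an organic anion transporter, was at -1.83 ± 0.36 and the leptin receptor gene Lepr at -1.82 ± 0.33 (log2, SE, authors' deposited table).

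Gene lists fixed before the data were examined were compared with all other tested genes. Of 48 lists with at least 4 tested members, 20 passed at an adjusted p below 0.05, with 10 positive and 10 negative. Some genes, such as Cps1, stand in several lists, so the lists are not independent of one another. Members named beside lists after the 10 with the smallest p, and beyond the first pair of each list, were chosen after their values were seen.

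**Figure D2:**
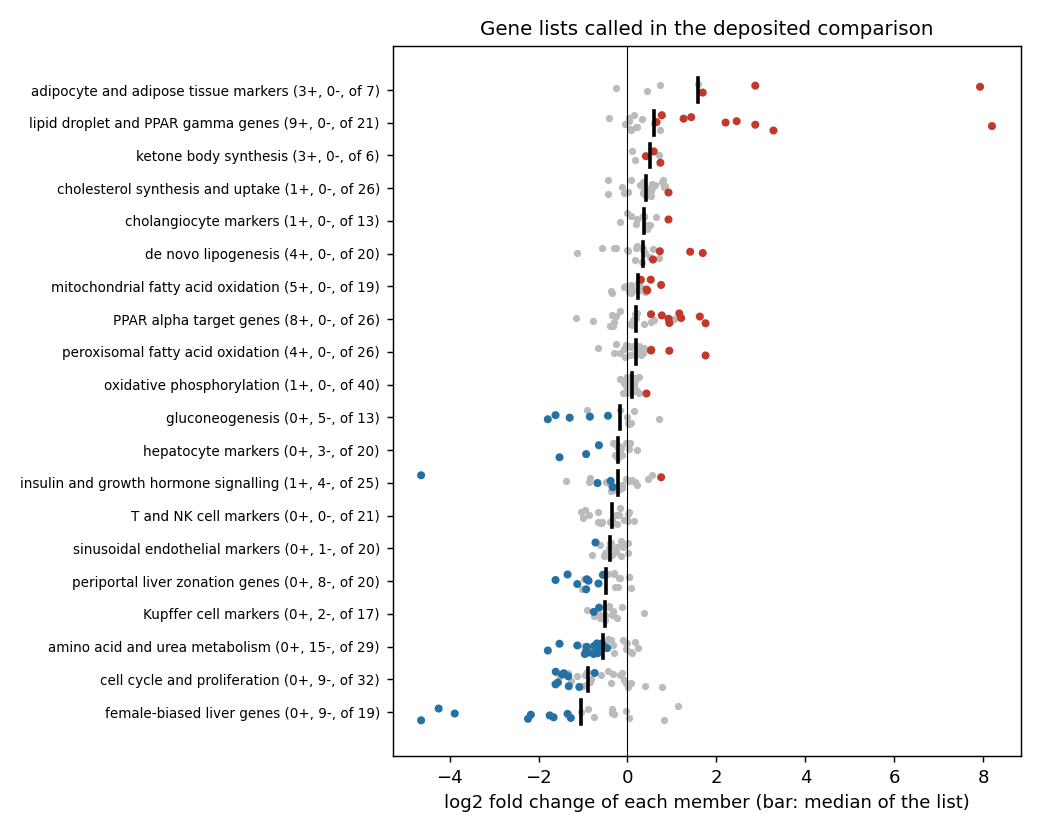
Log2 fold change of every tested member (points, horizontal axis) of the 20 gene lists that passed the list test, with the median of each list as a black bar. Red and blue points are members with an adjusted p below 0.05, and the label of each list gives their number per direction and the number of tested members.

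Lipid storage genes made up the list with the smallest p (adjusted p = 2.4e-15). Of 21 tested lipid droplet and PPAR gamma genes, 9 were called positive and 0 negative over all genes, and 10 positive and 1 negative adjusted over the list alone, with a median log2 fold change of 0.61. Besides Cidea, the monoacylglycerol acyltransferase gene Mogat1 was at 3.28 ± 0.32, Fitm1 at 2.46 ± 0.26 and the fatty acid transporter gene Cd36 at 1.43 ± 0.26 (log2, SE) in the authors' deposited table. Of 7 tested adipocyte and adipose tissue markers, 3 were called positive (Cfd, Cidec and Thrsp) and 6 were positive adjusted over the list alone (median 1.59, adjusted p = 4.6e-09). The mean normalized counts of the adipocyte genes Adipoq, Retn and Plin1 in the authors' deposited table were 0.387, 0.558 and 0.439, beside 395.2 for Cfd, and none of the 3 had an adjusted p there. Of 20 de novo lipogenesis genes, 4 were called positive and 0 negative, and 6 positive and 1 negative adjusted over the list alone (median 0.34, adjusted p = 0.00116). Srebf1, a regulator of fatty acid synthesis, was at 1.41 ± 0.23 and Thrsp at 1.69 ± 0.49 (log2, SE) in the authors' deposited table. The enzyme genes Fasn at 0.52 ± 0.30 (adjusted p = 0.352) and Acly at 0.58 ± 0.27 (adjusted p = 0.205) were not called there (log2, SE). Scd1, with a mean normalized count of 137690, was at -1.14 ± 0.47 (log2, SE, adjusted p = 0.136) and was the negative member adjusted over the list alone. In sign, 15 of the 20 genes were positive. Cholesterol synthesis and uptake genes had a median of 0.41, with 22 of 26 positive in sign, 1 called (Fdps) and 0 adjusted over the list alone (adjusted p = 0.00302). With the correlation preset at 0.10, the adjusted p was 0.0823 for de novo lipogenesis and 0.139 for cholesterol synthesis and uptake.

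Genes of fatty acid oxidation shifted to the positive side by smaller amounts. Of 26 tested PPAR alpha target genes, 8 were called positive and 0 negative, and 9 positive and 1 negative adjusted over the list alone (median 0.20, adjusted p = 0.000943). Vnn1 was at 1.63 ± 0.28, the peroxisomal protein gene Pex11a at 0.94 ± 0.17 and the thiolase gene Acaa1b at 1.76 ± 0.33 (log2, SE, authors' deposited table). For peroxisomal fatty acid oxidation, 4 of 26 genes were called positive and 0 negative, with the same counts adjusted over the list alone (median 0.18, adjusted p = 0.000962). Catalase, Cat, was at 0.22 ± 0.14 (log2, SE, adjusted p = 0.400) in the authors' deposited table. For mitochondrial fatty acid oxidation, 5 of 19 genes were called positive and 0 negative, and 7 positive and 1 negative adjusted over the list alone (median 0.24, adjusted p = 0.000967), among them Eci1 and Acads. With the correlation preset at 0.10, the adjusted p was 0.09065 for PPAR alpha targets, 0.09065 for peroxisomal and 0.0771 for mitochondrial fatty acid oxidation. All 6 ketone body synthesis genes were positive in sign and 3 were called, with 4 adjusted over the list alone (median 0.50, adjusted p = 0.000625). Acat1 was at 0.41 ± 0.11 and Bdh1 at 0.74 ± 0.20 (log2, SE) in the authors' deposited table. Oxidative phosphorylation genes had a median of 0.095, with 1 of 40 called (Ndufa2), 0 adjusted over the list alone and an adjusted p of 0.0471, which became 0.2275 with the correlation between genes preset at 0.05, 0.247 with the trend on GC content, length and abundance removed and 0.0775 with a mean normalized count of at least 100.

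Amino acid and urea metabolism had the smallest p of the negative lists (adjusted p = 4.0e-15). Of 29 tested genes, 15 were called negative and 0 positive, and 20 were negative adjusted over the list alone, with a median log2 fold change of -0.55. Tat, the tyrosine aminotransferase gene, was at -1.53 ± 0.23, Cps1, the entry enzyme of the urea cycle, at -0.93 ± 0.15 and the glutaminase gene Gls2 at -0.91 ± 0.15 (log2, SE) in the authors' deposited table. Cps1 (ENSMUSG00000025991) lies on chromosome 1 from 67123026 to 67231259 and Tat (ENSMUSG00000001670) on chromosome 8 from 109990437 to 109999803 in GRCm38. Of 20 periportal zonation genes, which include Cps1 and Gls2, 8 were called negative and 0 positive, and 9 negative adjusted over the list alone (median -0.49, adjusted p = 1.4e-10). Of 20 hepatocyte markers, 3 (Tat, Cps1 and Ahsg) were called negative and 0 positive, and 4 were negative adjusted over the list alone (median -0.21, adjusted p = 0.000145). With genes in 1 list only, the adjusted p was 0.000107 for amino acid and urea metabolism, 0.03655 for periportal genes and 0.0402 for hepatocyte markers.

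Genes of glucose metabolism did not move as 1 block. Of 13 gluconeogenesis genes, 5 were called negative and 0 positive, and 6 were negative adjusted over the list alone (median -0.17, adjusted p = 0.000111, and 0.0902 with ranks in place of the statistic). Pck1, the cytosolic enzyme that makes phosphoenolpyruvate, was at -1.62 ± 0.24 and the aspartate aminotransferase gene Got1 at -1.79 ± 0.30 (log2, SE) in the authors' deposited table. Pck1 (ENSMUSG00000027513) lies on chromosome 2 from 173153048 to 173159273 in GRCm38. The coactivator gene Ppargc1a was at -1.30 ± 0.22 and Fbp1 at -0.44 ± 0.11, while G6pc, the glucose-6-phosphatase gene, was at -0.90 ± 0.38 with an adjusted p of 0.144 (log2, SE, authors' deposited table).

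Of 22 glycolysis genes, 1 was called positive and 1 negative (Ldhb), with the same counts adjusted over the list alone, and the list had a median of 0.12 and an adjusted p of 0.162. Restricting the test to genes with a mean normalized count of at least 100 gave an adjusted p of 0.0438 for this list. Pklr, the liver pyruvate kinase gene, was at 0.72 ± 0.29 (adjusted p = 0.128) and Hk2 at 0.93 ± 0.40 (adjusted p = 0.160) in the authors' deposited table (log2, SE). Ldha was at 0.34 ± 0.19, the glucose transporter genes Slc2a1 and Slc2a2 at 0.11 ± 0.32 and 0.45 ± 0.23, and Pdk4 at 0.19 ± 0.30, each with an adjusted p above 0.05 in the authors' deposited table (log2, SE). Glucose and monosaccharide transport had 0 of 12 genes called, 0 adjusted over the list alone, and an adjusted p of 0.470. For the pentose phosphate pathway 1 of 11 genes (Taldo1) was called positive, with 2 positive and 1 negative adjusted over the list alone (adjusted p = 0.0661). Pyruvate oxidation and the TCA cycle had 2 genes called positive and 1 negative of 29, with 3 and 1 adjusted over the list alone (adjusted p = 0.119), and glycogen metabolism 1 positive of 16, with 1 adjusted over the list alone (adjusted p = 0.838).

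**Figure D3:**
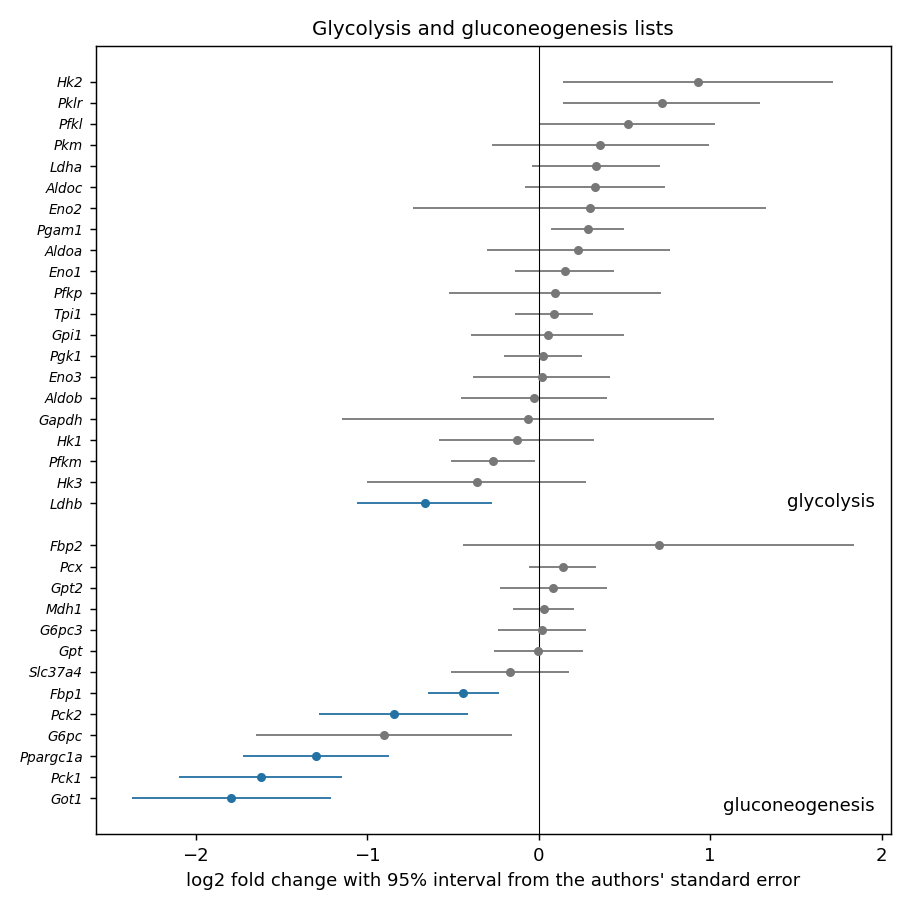
Log2 fold change (points, horizontal axis) with the 95% interval from the authors' SE (lines) for 21 genes of the glycolysis list and 13 of the gluconeogenesis list. Coloured genes had an adjusted p below 0.05, which holds for 5 gluconeogenesis genes, all negative, and for Ldhb (negative) among the glycolysis genes drawn.

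Female-biased liver genes were higher on the negative side. Of 19 tested, 9 were called negative and 0 positive, and 10 were negative adjusted over the list alone (median -1.06, adjusted p = 1.3e-10). Cyp2c40 was at -3.89 ± 0.43 and Cyp2c69 at -4.25 ± 0.58 (log2, SE) in the authors' deposited table, values that are uncertain where reads are shared with other Cyp2c copies. Of 24 male-biased genes, 5 were called positive and 1 negative, and 6 and 1 adjusted over the list alone, with an adjusted p of 0.0729 for the list. Cyp4a12a was at 1.55 ± 0.21 and Tff3 at -1.73 ± 0.37 (log2, SE, authors' deposited table). Insulin and growth hormone signalling had 1 gene called positive (Stat5a) and 4 negative, among them Cux2 and Igf1, of 25, with the same counts adjusted over the list alone. That list had a median of -0.22 and an adjusted p of 0.0211, which became 0.118 with the correlation preset at 0.05, 0.0630 with genes in 1 list only and 0.0762 with the trend on GC content, length and abundance removed. Of 5 tested sex chromosome dosage genes, 0 were called and 0 adjusted over the list alone (adjusted p = 0.797).

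Cell cycle genes were higher on the negative side, with 9 of 32 called negative and 0 positive, and 19 negative adjusted over the list alone (median -0.88, adjusted p = 7.6e-09). Mki67, a marker of dividing cells, was at -1.47 ± 0.37 and the spindle checkpoint gene Bub1b at -1.62 ± 0.34 (log2, SE) in the authors' deposited table. The mean normalized count was under 100 for 27 of these 32 genes, and with genes of a mean normalized count of at least 100 alone the list had an adjusted p of 0.384.

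Markers of several liver cell types differed as lists. Kupffer cell markers had a median of -0.50, with 2 of 17 called negative, 3 adjusted over the list alone and an adjusted p of 0.00015. Of those called, Fcna was at -0.64 ± 0.19 and Timd4 at -0.76 ± 0.26 (log2, SE, authors' deposited table). Sinusoidal endothelial markers had a median of -0.38, with 1 of 20 called negative (Bmp2), 1 adjusted over the list alone and an adjusted p of 0.000962. T and NK cell markers had a median of -0.36, with 0 of 21 called, 0 adjusted over the list alone and an adjusted p of 0.0211, which became 0.109 with the correlation preset at 0.05. Cholangiocyte markers had a median of 0.37, with 1 of 13 called positive (Krt8), 1 adjusted over the list alone and an adjusted p of 0.00675. With the correlation preset at 0.10, the adjusted p was 0.0771 for sinusoidal endothelial and 0.09065 for cholangiocyte markers. Neutrophil markers had a median of -0.89, with 3 of 14 positive in sign, 0 called, 0 adjusted over the list alone and an adjusted p of 0.0815. That list passed with ranks in place of the statistic (adjusted p = 0.0319), with every gene of the table as background (0.0180) and with the trend on GC content, length and abundance removed (0.00834). Stellate cell markers (0 of 18 called, adjusted p = 0.335) and B and plasma cell markers (0 of 15, adjusted p = 0.269) did not pass, with 0 adjusted over the list alone for both. Monocyte and lipid-associated macrophage markers had 1 of 22 called positive (Mmp12), 1 adjusted over the list alone and an adjusted p of 0.414, which became 0.0446 on the negative side with a mean normalized count of at least 100. Erythroid markers had 0 of 10 called, 1 negative adjusted over the list alone and an adjusted p of 0.712.

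Of the panel of 6 genes fixed for DEN, Mgmt was called positive and Mki67, described with the cell cycle genes, negative. Of 28 p53 and DNA damage response genes, 3 were called positive and 1 negative, and 5 and 2 adjusted over the list alone (adjusted p = 0.797). Cdkn1a was at 0.28 ± 0.48 and Mdm2 at 0.00 ± 0.10 (log2, SE), both with adjusted p above 0.05 in the authors' deposited table. Afp was at 0.12 ± 0.23 and Cyp2e1, an enzyme that activates DEN, at -0.03 ± 0.14, while Mgmt, a repair gene for alkylated guanine, was at 0.61 ± 0.16 (log2, SE, adjusted p = 0.00451) in the authors' deposited table. DNA alkylation and excision repair had 1 gene called positive and 2 negative of 23, with the same counts adjusted over the list alone (adjusted p = 0.757). Oncofetal and hepatocellular carcinoma markers had 1 positive and 2 negative of 24, with 2 and 3 adjusted over the list alone (adjusted p = 0.889).

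The other lists did not pass the test. Pericentral and Wnt zonation genes had 4 called positive and 1 negative of 20 (5 and 2 adjusted over the list alone, adjusted p = 0.144), and unfolded protein and integrated stress response genes had 2 positive of 26 (4 adjusted over the list alone, adjusted p = 0.144). NRF2 and antioxidant genes had 4 positive and 3 negative of 28 (5 and 3 adjusted over the list alone, adjusted p = 0.165). Xenobiotic cytochrome P450 genes and CAR or PXR targets had 2 positive and 2 negative of 24 (2 and 6 adjusted over the list alone, adjusted p = 0.189). Interferon-stimulated genes had 1 negative of 32 (1 adjusted over the list alone, adjusted p = 0.265), and fibrosis and extracellular matrix genes 2 positive and 1 negative of 31 (2 and 1 adjusted over the list alone, adjusted p = 0.453). Apolipoproteins and lipoprotein metabolism had 1 positive and 1 negative of 23 (the same adjusted over the list alone, adjusted p = 0.469), and bile acid synthesis and transport 2 negative of 19 (2 adjusted over the list alone, adjusted p = 0.469). Heat shock genes had 1 positive of 15 (1 adjusted over the list alone, adjusted p = 0.525), and acute phase genes 1 positive and 1 negative of 27 (the same adjusted over the list alone, adjusted p = 0.643). The circadian clock (20 genes, adjusted p = 0.469), inflammatory cytokines and chemokines (26 genes, adjusted p = 0.497) and MHC class II and antigen presentation (12 genes, adjusted p = 0.552) had 0 called by either adjustment. Pancreatic acinar markers (3 tested, 0 called, 1 negative adjusted over the list alone) and skeletal muscle markers (2 tested, 0 called by either adjustment) had too few tested members for the list test. With every gene of the table as background, the pentose phosphate (adjusted p = 0.0153), TCA cycle (0.0305), NRF2 (0.0407), male-biased (0.0141), pericentral (0.0417) and unfolded protein (0.0417) lists passed on the positive side. The median and the test differed in sign for bile acid synthesis (median 0.01), heat shock (median -0.01), DNA repair (median 0.02), p53 (median -0.02), glycogen (median -0.05) and oncofetal genes (median 0.06).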

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

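All alternatives here were chosen after seeing the data, since those planned before (other normalizations and count filters, DESeq2, limma-voom, other dispersion settings and sample subsets, the block, each library left out, fry and an estimated correlation) need values per sample that could not be matched and were not run. No paired analysis was possible because no column of the table carries a replicate number. The count of 1070 genes became 491 at an adjusted p below 0.01, 272 with a change of at least 2-fold, and 142 (89 positive, 53 negative) with the statistic divided by its median absolute deviation. The first and the second are stricter by construction, and for the last the division lowers every statistic. The other counts were 768 with Benjamini-Hochberg over every gene of the table, 1075 and 847 with a mean normalized count of at least 10 and 100, and 885 with the trend on GC content, length and abundance removed. Of the 41 named genes, 3 lost their call with the adjustment over every gene (among them Timd4) and 11 with the scaled statistic. Among the latter were Mki67 (adjusted p = 0.266), Mgmt (0.301), Hamp2 (0.348), Bub1b (0.0858), Fcna (0.459), Timd4 (0.622) and Acat1 (0.351). The 20 called lists became 17 with a preset correlation of 0.05 and 10 with 0.10, a higher preset widening the null by construction. Those lost at 0.10 were de novo lipogenesis, cholesterol synthesis, both fatty acid oxidation lists, PPAR alpha targets, oxidative phosphorylation, and the sinusoidal, T and NK, cholangiocyte and insulin lists, with adjusted p from 0.0771 to 0.446. The number was 20 with ranks, where gluconeogenesis was lost and neutrophil markers were gained, 27 with every gene as background, 19 with a mean count of at least 100, 19 with genes in 1 list only and 19 with the trend removed. No called list changed direction under the alternatives run on lists. The named genes were run under the adjustment over every gene and the scaled statistic alone, neither of which can change a sign.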

Other observations

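The gene families, the test of the unnamed sides, the test of adipocyte gene levels, the test of Xist and the test of hepatocyte share were chosen after the results were seen. Major urinary protein genes, which growth hormone controls in male liver, were higher on the positive side. Of 19 tested, 9 were called positive and 0 negative in the authors' deposited table, with a median log2 fold change of 1.01. The family had an adjusted p of 1.7e-13 over 5 families tested with limma's cameraPR, and 1.1e-08 with a preset correlation of 0.05. Mup17 was at 1.83 ± 0.35, Mup20 at 1.02 ± 0.18 and the more abundant Mup3 at -0.16 ± 0.20 (log2, SE, authors' deposited table), and reads shared between copies make single values uncertain. Of 13 Cyp2c genes, 3 were called negative and 0 positive (median -0.32, adjusted p = 2.7e-07, and 2.9e-05 with a preset correlation of 0.05). Cyp2c40 and Cyp2c69 also stand in the female-biased list, so this family is not separate evidence. Likewise, Mup3, Mup7, Mup20 and Mup21 stand in the male-biased list, which did not pass the list test (adjusted p = 0.0729). Copies that share reads are not independent, and their correlation could not be estimated. The adjusted p of the Mup and Cyp2c families may therefore be too small.

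Mitochondrial ribosomal protein genes, encoded in the nucleus, shifted to the positive side by a small amount. Of 74 tested, 67 were positive in sign and 12 were called positive, with 0 negative (median 0.16, adjusted p = 4.7e-11, and 6.8e-05 with a preset correlation of 0.05). No p with the trend on GC content, length and abundance removed is available for the families. Removal of that trend cost the oxidative phosphorylation list its call (cameraPR, adjusted p = 0.247), so a part of the trend in this small shift cannot be excluded. Of 77 cytosolic ribosomal protein genes 0 were called (median 0.00, adjusted p = 0.861), and of 25 mitochondrially encoded genes 0 were called (median -0.08, adjusted p = 0.418).

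Lipid droplet and adipocyte genes were higher on the positive side. Adipose tissue carried over with the liver would bring the abundant adipocyte transcripts Adipoq, Retn and Plin1, but the highest of their mean normalized counts was 0.141% of that of Cfd, which argues against it. A test on the fold change of Adipoq, chosen before, was void, since its mean normalized count of 0.387 lies at the floor. A trend with GC content, length or abundance as the whole cause is argued against by the adjusted p of 2.2e-14 for the lipid droplet list after the trend was removed. A candidate explanation is that high fat diet is the positive side, given the median of 0.61 for that list, but while the name of the deposited table mentions high fat diet, neither it nor any column names the sides, so diet and other contrasts cannot be told apart.

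Female-biased genes were higher on the negative side, and a trend with GC content, length or abundance is argued against as the whole cause by an adjusted p of 9.7e-12 after its removal. Whether there were more females on the negative side was not settled by the test on Xist. Its lower 95% bound was -1.64, below the list's median of -1.06. However, its mean normalized count lies near the lowest among tested genes, 2.949, so this interval cannot decide. The mean normalized count of Xist, an RNA that female cells make, was 3.24 beside 1717 for Ddx3y, which speaks against a female library, but no library known to be female sets the level to be reached. The Y-linked genes were examined once Xist had left this open, and 3 of 4 had an upper 95% bound below the log2 fold change of 0.19 that 1 female among 8 libraries gives, but 1 of 4 did for 12 libraries, and the number of libraries per side is not known, so they do not settle it. Sex is not in the labels, and a response of these genes to diet or DEN was not tested.

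Amino acid and urea genes were higher on the negative side, as were hepatocyte markers (adjusted p = 0.000145, and 0.0326 with a preset correlation of 0.10). Both lists hold Tat and Cps1, and with genes in 1 list only the hepatocyte markers had an adjusted p of 0.0402. That hepatocyte markers were negative as a list goes with a lower share of hepatocytes on the positive side. Such a share would also raise markers of the other cell types there, but 3 of 5 such lists were called negative and cholangiocyte markers positive, which argues against it as the whole cause. This rests on the preset correlation, since 2 of the negative lists passed at 0.05, and at 0.10 Kupffer markers alone (adjusted p = 0.0273), with cholangiocyte markers at 0.09065. A trend with GC content, length or abundance is argued against by an adjusted p of 3.9e-14 after its removal. A response of this pathway to diet or to DEN may account for the pattern and is a hypothesis that could not be tested without the sides of the comparison.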
